A study of Homo sapiens with 2 samples.

How the data were processed

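Binding was measured on DNA arrays carrying 1024 contexts of a lesion, 5′-NNXNNN-3′, with 1 array for human TDG and 1 for human UNG2. Both proteins were made in E. coli, per the labels. The labels name a fluorescent antibody against the His tag for TDG and an N-terminal fluorescein for UNG2. Whether the UNG2 array was read by its fluorescein directly or through an antibody was not settled. The values are the authors' deposited natural log of fluorescence intensity, normalized, per the file headers, with 1 value per context. The series' design text gives 7 to 10 spots per probe, and the values are already combined over them. How spots were combined, how background was treated and how the arrays were normalized is not given in the sources used here. Per-spot values and control probes without the lesion are not analysed here, so the error of a context and the signal over background are unknown. The number of arrays limits the precision.

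No value was transformed or filtered for the main results. A base effect is the mean of the 256 contexts with a base at a position minus the mean of the array. Its error is the residual SD of a least-squares model with all pairs of positions divided by the square root of the number of contexts. Matched sets are the 256 groups of 4 contexts that differ at 1 position. Folds are exponentials of differences of the natural log values. Models with single bases, pairs and triples were compared by R2 and by R2 in 10-fold cross-validation (seed 1). A pair effect is the mean of 64 contexts minus the sum of the array mean and both base effects. List medians were ranked among 10000 random lists of the same size, and the central range runs from percentile 2.5 to 97.5. Correlations were set against 10000 shuffles of contexts. Between proteins each array was scaled to a mean of 0 and an SD of 1. Contexts are not replicates, so these ranks and ranges describe the arrays and are not p-values.

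The contexts named were fixed by rule before the data were examined: per protein the 10 highest and 10 lowest, for the difference of scaled values the 5 highest and 5 lowest, every base effect at −1 and +1 with the highest and lowest base elsewhere, the 5 largest pair effects per protein, and each of the 16 lists. Ties were broken alphabetically. The alternatives tried were ranks, medians, leaving out the outermost 2.5% of contexts on each side or contexts with a run of 4 equal bases, linear intensity, lists matched on G and C content or on the bases at −1 and +1, and other shares for the overlap.

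The scripts were tested on simulated arrays. All 20 simulated base effects were recovered within 2 errors for each protein, and a noise SD of 0.162 was recovered as 0.164 for TDG and one of 0.265 as 0.276 for UNG2. A test of a curved relation, used in the closing observations for TDG, was checked on simulated data made by a curve alone and by pairs alone. The shape of the simulated curve was changed 2 times, because with the earlier shapes pairs gained nothing over single bases and the share tested was undefined. With the final shape the curve reached 120% of the gain of pairs in curve-made data and 3.62% in pair-made data, fitting all pairs over 1024 contexts. In the pair-made data pairs gained 11.9 percentage points over single bases, more than on the TDG array, where R2 in cross-validation went from 89.4% to 95.2%. No mixture of a curve and pairs was simulated, so the check does not show how the test performs on an array like TDG's. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.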

Results

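The binding of 2 human uracil-excising DNA glycosylases to a base analogue was measured on DNA arrays holding every combination of bases around a fixed lesion. The lesion, X, was the 2′-fluoroarabino analogue of deoxyuridine, which glycosylases can bind and which resists excision, and it was paired with G. The library varied 2 bases on the 5′ side and 3 bases on the 3′ side, 5′-NNXNNN-3′, giving 1024 contexts, and positions are counted from X as −2, −1, +1, +2 and +3. TDG (thymine DNA glycosylase, which removes thymine and uracil mispaired with G) was full length and carried a His tag, for which the labels name a fluorescent antibody. UNG2 (the nuclear form of uracil DNA glycosylase) was full length and carried fluorescein at its N terminus, with its endogenous cysteines replaced by alanine. Each protein had 1 array, so no value has a replicate array behind it and no p-value is given across contexts. The oligonucleotides are synthetic and have no genomic position. The question was how far the bases around the lesion set the binding of each protein.

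The TDG array had a median of 9.35 on the natural log scale of fluorescence intensity, an SD over contexts of 0.79, and values from 5.97 to 10.84. The UNG2 array had a median of 9.51, an SD of 0.52 and values from 2.88 to 10.57, and its second lowest value was 7.69. The contexts at the 95th percentile were 11.3-fold brighter than those at the 5th for TDG and 4.58-fold for UNG2. What a model of all pairs of positions left over had an SD of 0.16 for TDG, or 1.18-fold, and 0.27 for UNG2, or 1.30-fold. These residual SDs are averages over the array, which also hold any effect of 3 or more bases together, and do not bound the error of a single context: CCXCCC lay −10.3 and TCXTAA −5.85 residual SDs from the model for TDG. They gave errors of 0.010 for TDG and 0.017 for UNG2 on the mean of the 256 contexts that share a base at a position. The same error is given for every base, although the spread differed. For TDG the SD over contexts was 0.20 with G at +1 and 0.53 with C at +1. The pooled error may therefore be too large for G at +1 and too small for C at +1. AGXCGC lay −18.4 residual SDs from the UNG2 model, and in a fit without it the UNG2 residual SD was 0.20. This context therefore enlarged the UNG2 errors given here.

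TDG gave its highest signals where G followed the lesion, the arrangement left when the C of a CpG site is deaminated. The mean of the 256 contexts with G at +1 was 1.05 above the array mean, A at +1 was 0.20 above it, and T and C were −0.59 and −0.66 from it (error 0.010 each). G at +1 was thus 5.57-fold over C, 5.17-fold over T and 2.35-fold over A. G was the highest of the 4 bases at +1 in 256 of 256 matched sets, those of 4 contexts alike at every other position. The 171 leading contexts of the array all had G at +1, as did the 102 contexts of its top 10%. All 256 contexts of this kind lay above the array median. The lowest of them, CCXGTG, stood at 9.90 and the highest of the 768 other contexts, CAXAGA, at 10.36. Of those 768 contexts, 34 lay above CCXGTG and 0 above the median of the contexts with G at +1. CCXGTG and CAXAGA were picked out after their values were seen.

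The base 5′ of the lesion had a smaller effect on TDG. At −1, G was 0.20 and A 0.14 above the array mean, while T was at −0.05 and C at −0.30. G at −1 was 1.65-fold over C and exceeded it in 254 of 256 matched sets. At +2 the highest base was G at 0.26 and the lowest A at −0.10, although A, C and T lay within 0.02 of each other. At −2 A was highest at 0.10 and C lowest at −0.09, and at +3 C was highest at 0.11 and T lowest at −0.08. The sizes of some of these small effects depended on the setting: in SDs of the array, C at −2 went from −0.12 to −0.08 on ranks and −0.06 without the outermost contexts, and by medians A at +2 went from −0.12 to −0.21 and T at +3 from −0.11 to −0.06. The bases at +1 accounted for 78.3% of the variance over contexts, those at −1 for 6.13%, at +2 for 3.59%, at +3 for 0.967% and at −2 for 0.829%.

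**Figure D1:**
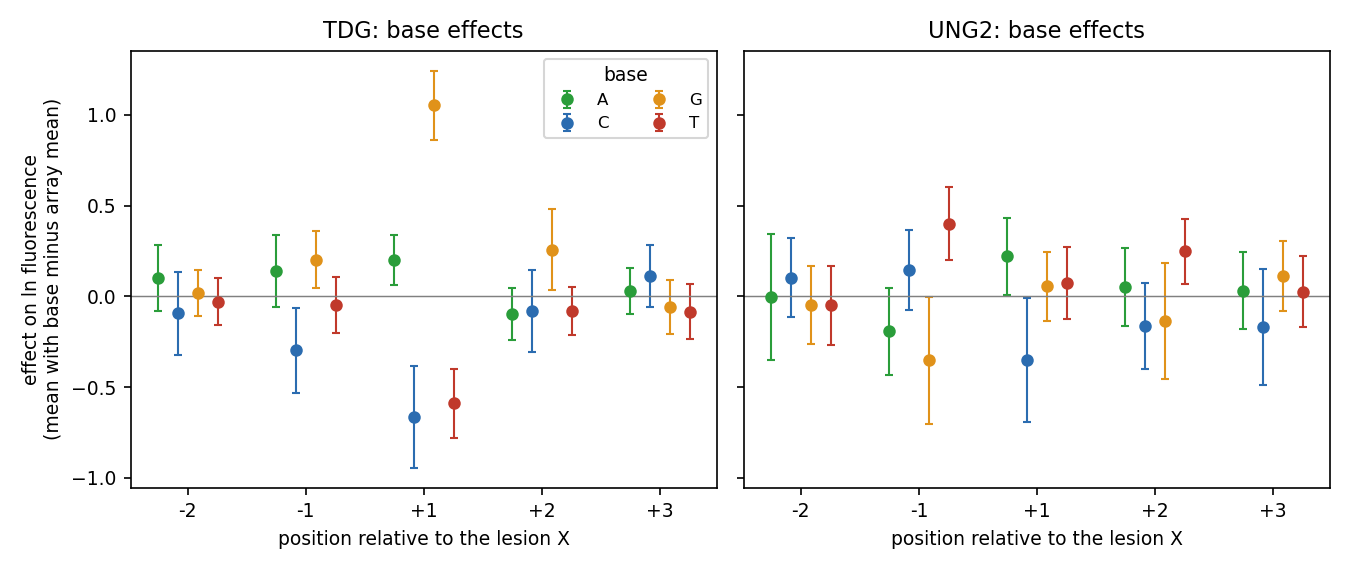
Base effects of TDG (left) and UNG2 (right), the mean natural log fluorescence of the 256 contexts with a base at a position minus the array mean, against the position relative to the lesion X; bars are the SD of the effect over 256 matched sets of contexts. G at +1 stands at 1.05 for TDG, and T at −1 has the highest value for UNG2, 0.40.

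The 10 brightest TDG contexts all had G at +1 and either G or A at −1. They were led by AGXGGA at 10.84, CAXGGC at 10.81 and CAXGGT at 10.81, followed by GGXGAA at 10.77, GAXGGA at 10.77, TGXGGC at 10.76, TGXGAT at 10.76, AGXGTA at 10.76, AGXGAT at 10.75 and GGXGGA at 10.75. These differ by less than the residual SD of 0.16, an average over the array, and their order is not given weight. Contexts with G at +1 spread less, with a total SD of 0.08 for G at −1 and 0.11 for A at −1. The 10 dimmest all had C at −1 and C or T at +1. CCXCCC was lowest at 5.97, followed by CCXTAT at 6.91, CCXCCT at 6.98, TCXCCT at 7.05, CCXCCA at 7.11, CCXTAG at 7.17, TCXTAA at 7.24, CCXCTT at 7.28, CCXCAA at 7.34 and CCXTTT at 7.41. CCXCCC lay −1.67 from its value in the all-pairs model. In the bottom 10% of the array, 65 of the 102 contexts had C and 37 had T at +1.

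Single bases at the 5 positions accounted for 89.8% of the TDG variance (89.4% in 10-fold cross-validation), and all pairs of positions raised this to 96.2% (95.2%). Adding triples did not raise the value in cross-validation further. The largest departures from additivity, in natural log units with an error of 0.020, were C at +1 with G at +2 (0.24), C at +1 with C at +2 (−0.24), C at −2 with A at −1 (0.22), G at +1 with G at +2 (−0.21) and A at −2 with A at −1 (−0.21). The highest base at −1 was 1.49-fold over the lowest among contexts with G at +1, and 2.10-fold among those with C at +1. At +2 the same ratios were 1.13 and 2.27. At −2 they were 1.07 and 1.42, and at +3 1.11 and 1.31. Only at −1 were the highest and lowest base the same with G as with C at +1. As a difference of linear intensity the order at −1 was the other way round, 13782 with G at +1 against 4491 with C at +1. It was also the other way round at +3 (3520 against 1972), and at +2 it was kept (4036 against 5596). At −2 the differences were close (1889 against 1686). No error was computed for differences of linear intensity. By these values the order at −1 and +3 depends on the scale, and at −2 that cannot be told.

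UNG2 depended most on the base 5′ of the lesion. At −1, T was 0.40 and C 0.15 above the array mean, while A was at −0.19 and G at −0.35 (error 0.017 each). T at −1 was 2.12-fold over G and exceeded it in 255 of 256 matched sets. At +1, A was at 0.22, T at 0.08 and G at 0.05, and C was at −0.35, so that A was 1.77-fold over C and exceeded it in 239 of 256 sets. T and G at +1 differed by 0.02, less than the error of 0.023 on a difference, an error that AGXCGC enlarged. At +2 T was highest at 0.25 and C lowest at −0.16, at +3 G was highest at 0.11 and C lowest at −0.17, and at −2 C was highest at 0.10 and T lowest at −0.05, although T and G there differed by only 0.002, less than that error. By medians, in SDs of the array, T at −2 went from −0.10 to −0.20, G at +1 from 0.11 to 0.06 and C at +3 from −0.33 to −0.20. Position −1 accounted for 32.4% of the variance, +1 for 17.1%, +2 for 10.3%, +3 for 4.04% and −2 for 1.46%.

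**Figure D2:**
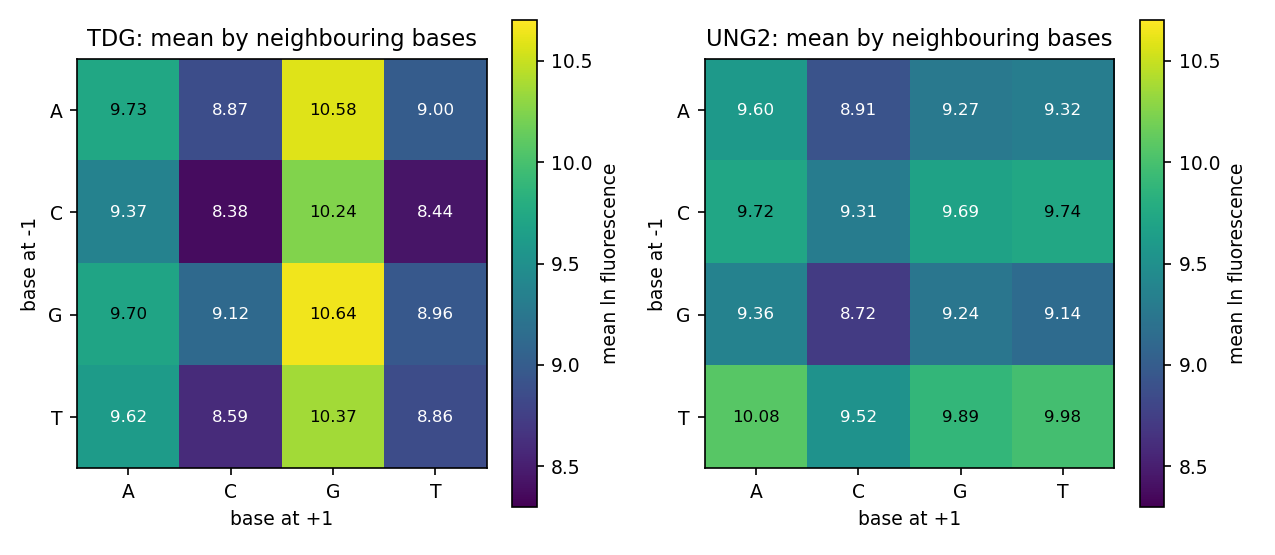
Mean natural log fluorescence of the 64 contexts with each pair of bases at −1 (rows) and +1 (columns) for TDG (left) and UNG2 (right), on one colour scale; levels are not comparable between the arrays. For TDG the column of G at +1 runs from 10.24 to 10.64, and for UNG2 the row of T at −1 runs from 9.52 to 10.08.

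The 10 brightest UNG2 contexts all had T at −1 and A or T at +1. They were ATXATT at 10.57, GTXAAT at 10.54, ATXTTG at 10.52, TTXATT at 10.51, ATXAGT at 10.51, ATXATG at 10.50, CTXATT at 10.48, TTXATG at 10.47, TTXAAT at 10.44 and GTXTTG at 10.41, again within the residual SD of 0.27 of each other. The dimmest had A or G at −1 and, with 1 exception, C at +1. AGXCGC stood alone at 2.88, and AGXTCC (7.69), GGXCGA (7.76), AGXCAA (7.87), GAXCGC (7.91), GGXCCT (7.95), TGXCGA (7.95), GAXCCA (8.00), AAXCCC (8.03) and GAXCTC (8.12) followed. Of the 102 contexts in the top 10%, 82 had T at −1, and of those in the bottom 10% 60 had G at −1 and 66 had C at +1.

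Single bases accounted for 65.3% of the UNG2 variance and all pairs for 76.2%. In cross-validation these were 63.9% and 69.8%, and triples lowered the value to 59.1%. The context AGXCGC weighed on these figures: without it single bases accounted for 72.5% and all pairs for 83.3%, an alternative chosen after the data were seen. The largest departures from additivity, with an error of 0.033, all involved −2 and −1. They were A with G (−0.22), T with C (−0.17), G with C (0.14), A with A (0.13) and T with G (0.13), the base at −2 given first. Their order depended on the scale: on ranks, in SDs, T with C was −0.42, G with C 0.32 and A with G −0.30. The lead of A with G also rested on AGXCGC, which is among its contexts. With AGXCGC set to its model prediction, an alternative chosen after the data were seen, A with G went from −0.43 to −0.33 SDs. T with C was then at −0.33.

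Lists of contexts fixed before the data were examined took neighbourhoods in which cytosine deaminates or is deaminated, contexts known as good or poor for uracil excision, and contexts of a given base composition. Each list's median was ranked among the medians of 10000 random lists of the same size, and 11 of the 16 lists fell outside the central 95% for each protein. The lists are not independent, and several lie within others. CpG is G at +1 and CpH all other contexts, and the list of T at −1 is that base alone, so their ranks largely restate the base effects above. The count does not tally separate results. For TDG the median of the CpG list was 3.13-fold over the array median (percentile 100), and that of the remaining contexts, CpH, was −0.26 from it (percentile 0). For UNG2 the same lists were at 1.03-fold (percentile 75.3) and −0.01 (percentile 12.9), inside the central range. That call did not hold under other settings: by the mean the lists reached percentiles 97.8 and 2.03, and among random lists matched on the number of G or C they reached 99.9 and 0.015, outside the central range.

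The lists of APOBEC3 targets, cytidine deaminases that act on single-stranded DNA, mostly after T, ranked high for UNG2. The list with T at −1 was 1.49-fold over the UNG2 median (percentile 100), and adding A or T at +1 gave 1.65-fold (100). The APOBEC3A-type list, YTXA, stood at 1.77-fold and the APOBEC3B-type list, RTXA, at 1.74-fold, and all 32 contexts of each lay above the array median. Among random lists matched on the bases at −1 and +1 these lists were at percentiles 56.6 and 46.0, inside the central range. The APOBEC3G list, CCX, was 1.41-fold over it (100). For TDG the lists with T at −1 and with T at −1 and A or T at +1 were inside the central range (percentiles 23.7 and 25.2), as was YTXA (82.8), but by its mean the list with T at −1 and A or T at +1 was outside it at 0.46. RTXA was just outside it at 1.41-fold (97.53), and CCX was −0.32 from the array median (0.31), with 23 of its 64 contexts in the bottom 10%.

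The lists for AID, the deaminase of antibody diversification, included a hot and a cold list that took opposite sides in the arrays. The hotspot list WRX was 1.19-fold over the TDG median (percentile 99.8) and −0.26 from the UNG2 median (0). Limiting it to C or T at +1 gave −0.35 for TDG (0) and −0.43 for UNG2 (0). The cold list SYX was −0.21 from the TDG median (0.03) and 1.33-fold over the UNG2 median (100). Among random lists matched on the bases at −1 and +1, WRX was at percentiles 86.0 for TDG and 70.1 for UNG2, and its form with C or T at +1 at 32.8 and 19.7, all inside the central range. SYX was inside it for UNG2 (96.6) and outside it for TDG (1.26). The list of contexts known as good for uracil excision by UNG enzymes, WXAW, was 1.67-fold over the UNG2 median (100), with 30 of 64 contexts in the top 10%, and the list of poor ones was at −0.13 (0). For TDG these were 1.21-fold (92.8, inside the central range) and −0.24 (0). The TDG value for WXAW went opposite ways with the matching of random lists, to percentile 99.97 on the number of G or C and to 0 on the bases at −1 and +1. With −1 and +1 matched, only A or T at +2 still sets this list apart. Among contexts with A at +1 these had the lowest TDG means at +2 (9.49 for A and 9.48 for T, against 9.87 for G and 9.58 for C). Percentile 0 thus largely restates the bases at +2.

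Among lists of composition, contexts of A and T alone were 1.65-fold over the UNG2 median (percentile 100), and those of G and C alone were at −0.10 (16.5). For TDG these lists were at −0.12 (28.3) and 1.60-fold (99.3; its mean reached only 91.1). Matched on the bases at −1 and +1, the TDG percentiles were 2.44 for A and T alone and 42.8 for G and C alone. Contexts of purines alone were 2.65-fold over the TDG median and those of pyrimidines alone were −0.98 from it (100 and 0), with 19 of 32 of the latter in the bottom 10%. Matched on −1 and +1 the purine list was at percentile 70.4 and the pyrimidine list at 0. For UNG2 these were −0.17 (4.38) and 1.11-fold (82.0), inside the central range. The number of G or C among the 5 flanking bases correlated with the value at r = 0.129 and rho = 0.132 for TDG and at r = −0.351 and rho = −0.364 for UNG2, across contexts, which are not independent replicates. With the bases at −2, +2 and +3 alone, r was 0.058 for TDG and −0.170 for UNG2.

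The comparison of the proteins asked whether they favoured the same contexts. Levels cannot be set against each other, because protein and label differ together and how each array was normalized is not known. Over 1024 contexts the arrays correlated at r = 0.0057 and rho = 0.0098, within the range of shuffled contexts (−0.062 to 0.062). Their top 10% of 102 contexts each shared 0, where 10.2 are expected of independent lists, and their bottom 10% shared 4. The ratio of shared to expected contexts depended on the share taken: it was 0 for the top 5% and 10% and 0.714 for the top 20% (29 shared), and 0.787, 0.394 and 0.738 for the bottom 5%, 10% and 20%. Within contexts of equal base at +1 the relation was negative, with r of −0.366 for A, −0.400 for C, −0.606 for G and −0.395 for T, each below the range of shuffles. These 4 values were computed after the data were seen. The residuals of the additive models correlated at −0.120, outside the range of shuffles, and those of the all-pairs models at −0.035, inside it. Over the 20 base effects r was 0.037 and rho −0.265.

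**Figure D3:**
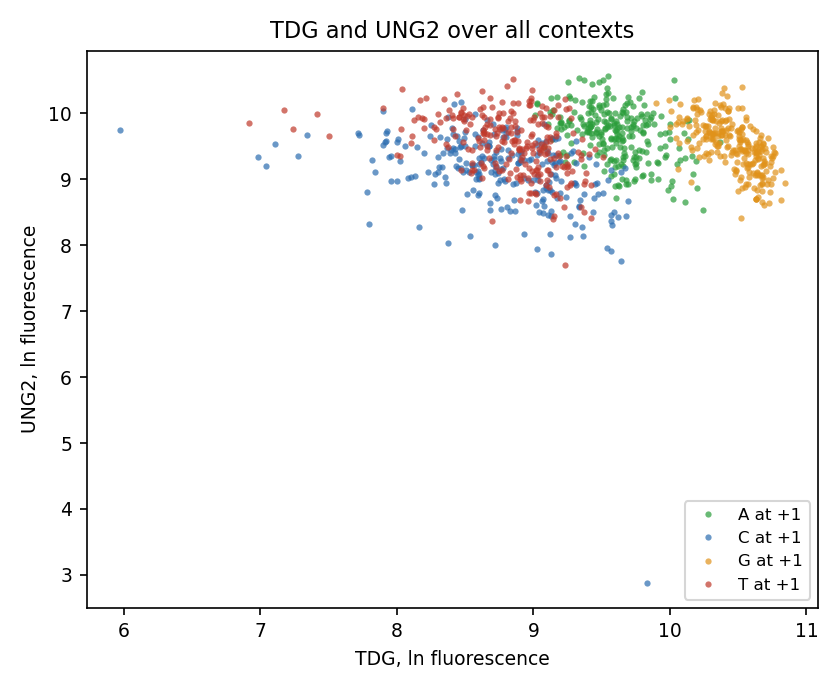
Natural log fluorescence of UNG2 (vertical) against TDG (horizontal), 1 point per context, coloured by the base at +1. Contexts with G at +1 lie at the right, above 9.89 for TDG, and slope downward (r = −0.606), and AGXCGC lies alone at 2.88 for UNG2.

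With each array scaled to a mean of 0 and an SD of 1, the base effects differed most for G at +1, by 1.23 SDs (TDG minus UNG2; error 0.035). They differed by 0.94 for G at −1, 0.55 for A at −1, −0.66 for C at −1, −0.84 for T at −1 and −0.90 for T at +1. A and C at +1 differed by −0.18 and −0.16, but these sizes depended on the scaling: A was at −0.08 on ranks, and C was at −0.03, within the error, with arrays scaled by the median and median absolute deviation. At the other positions the extremes were G (0.59) and T (−0.59) at +2, A (0.14) and C (−0.32) at −2, and C (0.47) and G (−0.29) at +3. At −2 the highest base depended on the setting: G passed A on ranks (0.12 against 0.08) and without AGXCGC (0.14 against 0.11), the latter chosen after the data were seen. The contexts ranked furthest above UNG2 on the TDG array were AGXCGC (13.3 SDs), GGXCGA (3.61), TAXGCC (3.47), AGXGAC (3.29) and CAXGGT (3.29). Those furthest the other way were CCXCCC (−4.90), CCXTAG (−3.97), CCXTAT (−3.93), CCXTTT (−3.54) and TTXTTG (−3.50). No replicate array exists against which to test these differences.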

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

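The tests of TDG's pairs with +1, of the TDG value of AGXCGC and of correlations within a base at +1 were chosen only after the results were seen. Base effects of opposite sign in the proteins, each outside the central 95% of random sets on its own array, were found for 7 bases. As TDG minus UNG2 in SDs of each array they were C at −2 (−0.32), A at −1 (0.55), C at −1 (−0.66), G at −1 (0.94), T at +1 (−0.90), G at +2 (0.59) and C at +3 (0.47). Other bases of opposite sign did not pass this rule. Among them, T at −1 was at −0.06 for TDG and 0.78 for UNG2 (−0.84), and T at +2 at −0.10 and 0.48 (−0.59). Their TDG means stood at percentiles 14.2 and 2.77 of random sets, whose spread includes that from the base at +1. The difference between the proteins was not tested, since each has 1 array.

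The arrays had an r of 0.0057 over all contexts and were negatively related within each base at +1, at r = −0.409 once both were centred on that base. At +1 the base effects of A, C and G had like signs in both proteins, and those of T opposite signs. At the other positions the signs were opposite, some effects being small, except for T at −2, C at +2 and A at +3. The r over all contexts thus combines effects of like and of opposite sign. Opposite bases favoured at −1 did not account for all of the negative relation: r was −0.266 after centring on −1 and +1, below the range of shuffles (−0.064 to 0.067). Nor did GC content: r was −0.413 after centring on +1 and on the number of G or C at the other positions (shuffles −0.069 to 0.077). For TDG, however, the numbers of G and of C went opposite ways (r of 0.484 and −0.335 across contexts). Centring on G or C together therefore says little about other measures of base composition. The shuffles treat contexts as interchangeable, although a few base effects make up most of the variance. Their ranges therefore describe the arrays and cannot decide whether unrelated base preferences would give such values. The detection and the normalization of each array cannot be separated from the proteins in this design. No biological explanation was tested.

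AGXCGC had a UNG2 value of 2.88, where the all-pairs model fitted without it gave 8.32. A probe defective on both arrays was argued against, since its TDG value was −0.020 residual SDs from its fitted value, but the labels do not say whether both arrays had the same design and print, and a defect of the UNG2 print is not excluded by this. A sequence effect of like size shared by its neighbours was argued against too: the 15 contexts that differ by 1 base had values from 8.37 to 9.35. Their median residual was −0.15 SDs. The model was fitted on these contexts too and takes up effects of bases and pairs, so this residual bears only on effects beyond pairs. A defect of its spots on the UNG2 array alone may remain, as may an effect of this exact sequence, and per-spot values are not analysed here.

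TDG's range from the lowest to the highest base was smaller in natural log units with G than with C at +1 at each other position. A curve such as saturation could give this. However, at −1 the range was smallest with A at +1 (0.37 against 0.40 with G, pooled error 0.029). At +3 it was largest with T (0.37 against 0.27 with C). With G and with C at +1 the same bases set the range only at −1. At +2, C was above T with G at +1 (10.48 against 10.38) but below it with C at +1 (8.42 against 8.68). One curve that only rises would keep their order, so alone it does not give this reversal. The reversal was picked out after the values were seen. On linear intensity the range was larger with G than with C at +1 for positions −1 and +3, and smaller for +2. At −2 it was close (1889 against 1686), and no error was computed for the linear ranges. By these values the pattern depends on the scale at −1 and +3, and at −2 that cannot be told. As first set up, before its result was seen, the test asked whether a cubic curve of a sum of base effects reached 80% or at most 50% of the gain in R2 that all pairs give in cross-validation. It reached 28.3% (SD 0.50 over 10 draws of the folds), and all pairs added 4.28 percentage points to the curve. All pairs also include pairs that the pattern does not concern, so the test was repeated for the pairs with +1, with the same bounds: the curve reached 49.2% (SD 1.10), and these pairs added 2.07 points to it. Taken alone 49.2% is under the bound of 50%, and it is left undecided only by a rule, added after the values were seen, that a bound be passed by 2 SDs; looser bounds, tried then too, are not used, and a curve as part of the cause stays open, beside specific pairs of bases as a hypothesis.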

How the results depend on the processing

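Of 355 alternatives, 323 kept the result within its bounds, 14 moved it, 10 ended and 8 gave a departure from random lists, and 0 reversed a called value. For a base effect the bound was the SD over matched sets, often larger than the effect, and for R2 and correlations the SD over folds. Such bounds are wide: TDG minus UNG2 for C at +1 went from −0.16 to −0.03 within a bound of 0.81. The count of 323 is therefore not a measure of how stable the results are. All 200 alternatives for base effects kept the sign. On linear intensity, chosen after the data were seen, TDG's variance explained rose to 94.2% for single bases and 98.5% for all pairs, and UNG2's to 73.2% and 85.4%; it replaced the planned power of 2, which was not run because the deposited log is natural. Of the 11 lists with a value once random lists were matched on −1 and +1, 6 stood outside the central range for TDG and 3 for UNG2. Unmatched it was 11 of 16 each, a count over more lists and not a like one. For TDG, RTXA, CCX, SYX and pyrimidines alone were outside both ways, while WXAW and A and T alone were outside only when matched. For UNG2, CCX, WXAW and A and T alone were outside both ways. The matching removes the bases that define most lists, and lists that fill whole groups have no matched value. TDG's WXAW list turned from percentile 92.8 to 0 under it, and rose to 99.97 matched on GC. With GC of −2, +2 and +3 only, r was −0.170 for UNG2 and 0.058 for TDG. The correlation of the proteins moved to −0.266 centred on −1 and +1, and to −0.366, −0.400, −0.606 and −0.395 within A, C, G and T at +1, the last 4 chosen after the data were seen. The overlap over that expected was 0.714 for the top 20% of contexts, 0.738 for the bottom 20% and 0.787 for the bottom 5%. Beyond the matching, and what it leaves of WXAW at +2, the cause was not tested. No paired analysis was possible because each protein has 1 array, and no replicate could be left out.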

Other observations

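The number of each base among the 5 flanking positions followed the value in different ways. For TDG, r across contexts was 0.484 with the number of G, −0.335 with C, −0.273 with T and 0.124 with A. For UNG2 it was 0.351 with T, −0.218 with C, −0.186 with G and 0.054 with A. These were computed after the data were seen, and G at +1 enters the first of them.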
